A study of Mus musculus with 14 samples.

How the data were processed

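The study measured RNA from colon cancers and from matched tumour-free colon mucosa of mice with Msh2 and Tgfbr2 inactivated in the intestinal epithelium, on an Affymetrix Mouse Gene ST 1.0 array for each of 14 samples, 7 per tissue. Total RNA was extracted from bulk tissue and labelled with biotin, per the labels' protocols. The authors deposited 1 table of 35556 rows, 1 per transcript cluster, and its values are log2 signals, as judged from their range of 2.39 to 14.5 and from the RMA method. The submitters' processing notes name RMA, which corrects background, normalizes by quantiles and summarises probes, and the R package oligo, whose versions are not given in the sources used here. Such normalization makes the distributions of the arrays alike, and array medians over all deposited rows lay between 6.69 and 6.85. Detection calls, scan dates and array batches are not given in the sources used here, so no batch could be tested, and no gene was called absent. Each array was tied to its sample by its column name, and its tissue was taken from the labels.

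Rows were named from the platform annotation supplied with the values. Exactly 1 gene symbol stood on 21789 rows, several on 1621 and none on 12146, and the rows without a single symbol were left out. Of the single-gene rows 21698 had an Entrez identifier in the reference gene table used here, and no symbol needed updating. For the 999 genes with more than 1 row the row with the highest mean over all 14 arrays was kept, which left 19938 genes. No filter on intensity was used. Gene coordinates are not reported, since no genome build is named in the sources used here.

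The tissues were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the values as deposited, with tissue as the only term and all 14 arrays in the fit. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Errors are the SD over 7 arrays or the standard error of the moderated fit, and fold changes are the antilog of the difference of mean log2 values. The groups, the test, the 36 gene lists, the rule for the genes named and the alternatives of the processing were chosen before the data were examined. The labels call the mucosa matched but do not tie the replicate numbers to animals, so the replicate number was used as a block only in an alternative.

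The lists held 600 entries for cell types of bulk colon and for pathways, of which 43 were not measured by a row with a single symbol, and 2 were matched through a synonym. They were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members were also adjusted over the list alone. Among the alternatives camera estimated the correlation from the data, and none of the 22 lists past the test at the preset correlation was past it then. The rule for the named genes took Tgfbr2 and Msh2, but Msh2 had no row with a single symbol and was not analysed. The rule also took the 12 genes with the largest increase and the 12 with the largest decrease among called genes with an established symbol. For each list it took the 2 called members with the largest difference in its main direction and 1 in the other direction. A list with no called member was represented by its member with the smallest adjusted p. Epcam, Krt8, Cdh1 and Mki67 fall outside this rule and were chosen after their values were seen.

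Alternatives were the replicate number as a fixed or a random block, 3 other scalings (median centring, quantile and cyclic loess), 2 filters on mean intensity, 2 other rules for genes with several rows, an intensity trend with robust variance, array weights, each array left out, an exact rank test, an adjusted p threshold of 0.01, a test against a 1.5-fold difference, and for lists ranks and the fry test. After the data were seen, fits without cancer 2 and both arrays numbered 5, fits without cancers 2 and 4, and an exact permutation test of each list mean were added. No detection call was at hand, so 3 Y-linked genes in the 6 arrays without Y-linked RNA were then also used. Their highest value there, 5.42, served as a rough floor for absent transcripts. It came from Kdm5d (5.04 to 5.42), while Eif2s3y and Uty were at 4.38 or below there, so the level of an absent transcript differs between genes. Where a named gene had an array at or below this floor in its dimmer tissue, that array was set to the floor. The fold is then given as a rough bound, which held for 11 named genes. Of the 3548 called genes 269 had a mean at or below the floor in at least 1 tissue and 145 in both.

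The fit was tested on simulated data of 19938 genes with 200 genes changed. It called 25 of 50 genes changed by 0.5 on the log2 scale, 37 of 50 changed by 1, 50 of 50 changed by 2 and 49 of 50 changed by 3, with 6 false calls, and camera called the 1 list of 36 that was shifted by 0.5 and none of the others. The simulated genes were drawn without the correlation between genes that the real lists have, so this does not test the calibration of camera on real lists. In 99 other splits of the real arrays into 7 and 7, a median of 14 lists were past the same test. No pair of arrays held the same values. Correlations between arrays over all deposited rows ranged from 0.962 to 0.990 within a tissue and from 0.941 to 0.982 between tissues. Pictures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.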

Results

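RNA from colon cancers and from matched tumour-free colon mucosa was measured on 14 whole-transcript expression arrays, 7 for each tissue. All of the tissue came from mice in which Msh2, a DNA mismatch repair gene, and Tgfbr2, the type II TGF-beta receptor gene, had been inactivated in the intestinal epithelium. The RNA was extracted from bulk tissue, so each value is the sum over the cell types in a piece. Values were log2 signals between 2.39 and 14.5, and 19938 genes were tested. The number of arrays limits the precision, since array signals carry no count of molecules. The labels number the arrays as replicates but do not say that each came from its own animal, so p-values measure the spread between these samples. The first principal component held 43.3% of the variance and separated the tissues, with the cancers between -56.4 and -15.5 and the mucosa between 9.64 and 50.1. Mucosa 1, at 9.64, lay nearest to the cancers.

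**Figure D1:**
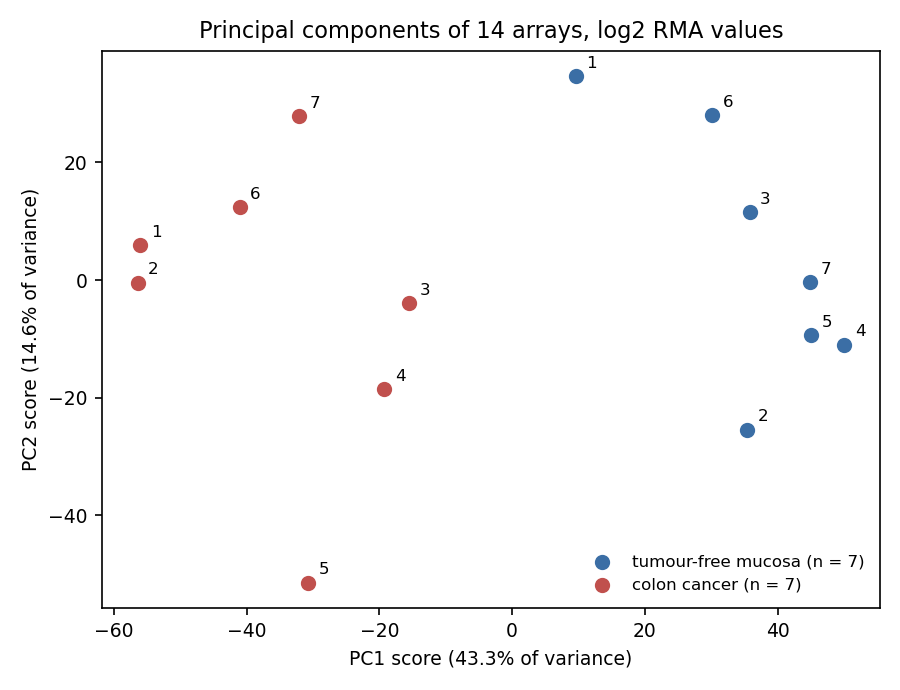
Scores of the 14 arrays on the first 2 principal components of the log2 values, with the share of variance on each axis and the replicate number beside each point. The 7 colon cancers lie between -56.4 and -15.5 on the first component and the 7 mucosa arrays between 9.64 and 50.1.

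The comparison asked which genes and cell type markers differed between the cancers and the matched tumour-free mucosa. Among the largest increases were Atp6v0d2, a subunit of the vacuolar proton pump of osteoclasts and macrophages, Gpnmb, a membrane glycoprotein of macrophages, and Mmp12, macrophage elastase. Atp6v0d2 was at 10.29 ± 1.17 (SD, n = 7) in the cancers and 4.81 ± 0.24 (SD, n = 7) in the mucosa. The mucosa signal was no higher than that of Y-linked genes in arrays without Y-linked RNA (3.89 to 5.42), and against 5.42 the difference was at least 29.3-fold. Gpnmb was 36.4-fold and Mmp12 36.0-fold higher, and for all 3 genes each of the 7 cancers lay above all 7 mucosa arrays. The largest decrease in measured signal among called genes with an established symbol was in Retnlb, a goblet cell product, which was 25.4-fold lower. Retnlb was at 8.15 ± 1.64 in the cancers and 12.81 ± 0.64 in the mucosa (SD, n = 7 each). Fabp2, the intestinal fatty acid binding protein, fell by 3.82 on the log2 scale and Slc9a3, a sodium-hydrogen exchanger of the absorptive epithelium, fell by 3.26. Without cancer 2 and both arrays numbered 5, Fabp2 fell by 4.48 and Slc9a3 fell by 3.84. Position along the gut, whose marker genes also differed between arrays, was not a term in the fit. By limma with Benjamini-Hochberg adjustment, 2021 genes were higher and 1527 lower in the cancers at an adjusted p under 0.05, of which 792 and 286 differed by at least 2-fold and 171 and 55 by at least 4-fold. In 1067 genes (5.35%) all 7 cancers lay outside the range of the mucosa, against 0.0583% by chance. The split of calls depended on the scaling: of the called genes 57.0% were higher with the values as deposited. Centring each array on its median over the genes tested, not over all deposited rows, moved the median of all genes by -0.14. This centring gave 1664 higher and 5475 lower, 23.3% higher.

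Beyond those genes, the 12 largest increases held Khdc1a (at least 26.9-fold, 3 of 7 mucosa arrays being at the level of absent transcripts), Col10a1, a collagen of hypertrophic cartilage (log2 difference 4.14, SE 0.58), and Itgb8, an integrin chain that takes part in activating latent TGF-beta (4.09, SE 0.39). They also held Serpinb11, Clu, the secreted chaperone clusterin (3.88), Aldh1a3, an enzyme of retinoic acid synthesis (3.76), and Msln, mesothelin (3.66). Serpinb11 was at 8.15 in the cancers and 4.11 in the mucosa, a signal within the range of absent Y-linked transcripts, and was at least 6.66-fold higher. C3ar1, the receptor for complement fragment C3a (3.57), and Cd84, a leukocyte surface receptor (3.52), completed the set. The adjusted p of these 12 genes was at most 0.000245 in limma, and each cancer lay above all mucosa arrays for every one of them. Col10a1 was at 7.43 in cancer 3 against 10.52 to 12.23 in the other cancers, and its difference was 4.73 without cancer 3. Khdc1a was at 8.89 in mucosa 1 against 4.25 to 6.00 in the other mucosa arrays. Among the 12 largest decreases were Apol10a (log2 difference -3.71, SE 0.27), the cytochrome P450 genes Cyp2c65 (-3.69, SE 0.52) and Cyp2c55 (-3.31, SE 0.53), and the glycosyltransferase genes A4gnt (-3.52, SE 0.31) and B3gnt6 (-3.48, SE 0.40). A4gnt and B3gnt6 add sugars to the O-glycans of mucins. Reg3b (-3.19) and Reg3g (-3.09), which encode antimicrobial lectins, and Abca12, a lipid transporter gene (at least 7.36-fold, with 1 cancer at that level), were lower too. Akr1c21, a hydroxysteroid dehydrogenase gene, was at 8.20 in the mucosa and 5.17 in the cancers, where 6 of 7 arrays lay within the range of absent transcripts, and was at least 6.81-fold lower. For Atp6v0d2, Khdc1a, Serpinb11, Abca12 and Akr1c21 the rank by size is therefore not settled. The adjusted p of the 12 decreases was at most 0.00727 in limma. Cyp2c55 with Cyp2c65, Reg3b with Reg3g, and Khdc1a belong to families of closely similar genes, so their probes may share signal.

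**Figure D2:**
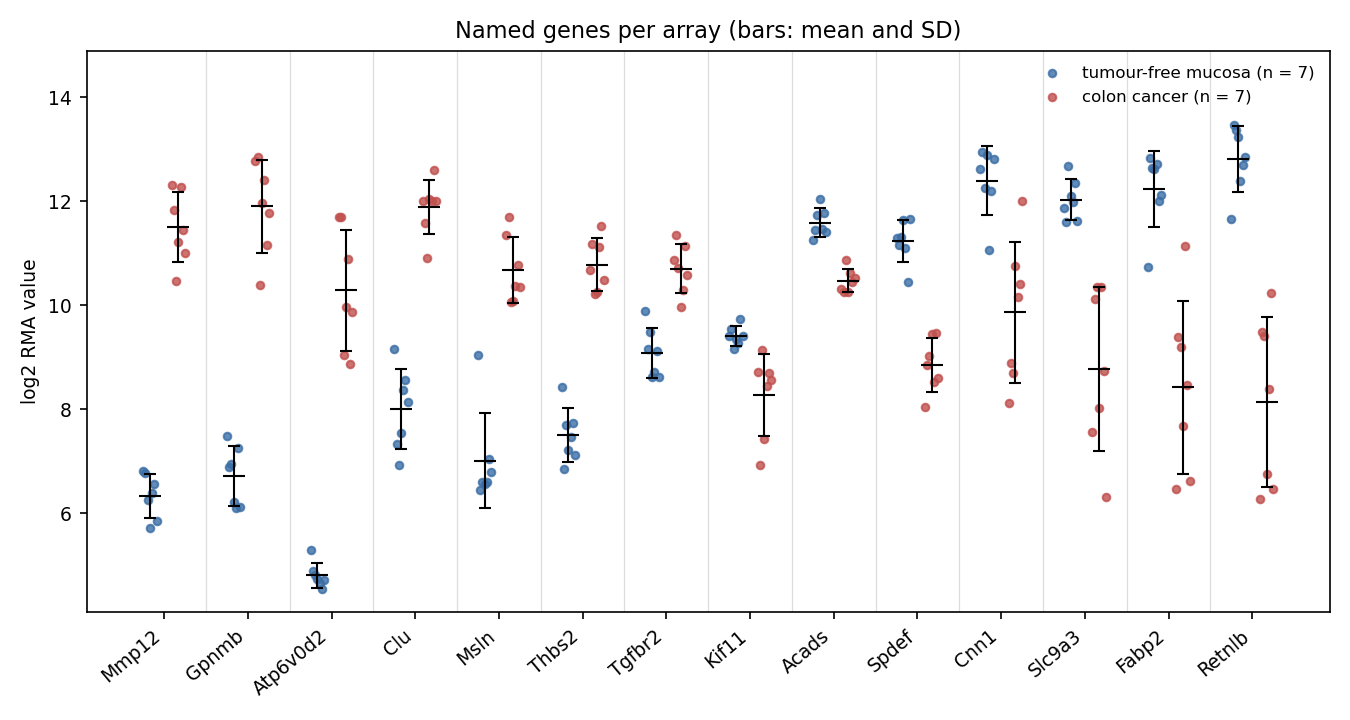
Log2 values of 14 named genes in each array, grouped by gene, with mucosa in blue, cancers in red and bars for the mean and SD of 7 arrays. Mmp12 lay at 11.51 ± 0.68 in the cancers and 6.34 ± 0.42 in the mucosa, and Retnlb at 8.15 ± 1.64 and 12.81 ± 0.64.

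Of the inactivated genes, Tgfbr2 was at 10.71 ± 0.47 in the cancers and 9.09 ± 0.48 in the mucosa (SD, n = 7 each). This was a log2 difference of 1.62 (SE 0.23), or 3.07-fold, with each cancer above all mucosa arrays (limma adjusted p = 0.000316, Benjamini-Hochberg). Msh2 had no row with a single symbol and was not analysed here. Both tissues came from inactivated mice and bulk tissue holds other cell types, so the Tgfbr2 signal does not test the inactivation.

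Genes of macrophages, of the extracellular matrix and its proteases, and of blood vessels were higher in the cancers. Of the 16 measured macrophage and monocyte genes 15 were higher and 1 was not past the threshold, led by Cd68, a lysosomal protein of macrophages (10.6-fold), and C1qc, a chain of complement C1q (6.90-fold). The count adjusted over the list alone was also 15, the mean log2 difference was 2.04, and the camera adjusted p was 5.71e-17, with an adjusted p = 0.124 with an estimated correlation. Of 16 matrix protease and inhibitor genes 13 were higher, 16 when adjusted over the list alone, and the mean was 2.18 (camera adjusted p = 9.74e-14, and adjusted p = 0.124 with an estimated correlation). Mmp12 and Ctsk, cathepsin K (10.4-fold), led this list. Of 21 fibroblast and extracellular matrix genes 16 were higher and none lower, 19 higher when adjusted over the list alone, with a mean of 1.35 (camera adjusted p = 9.31e-13, and adjusted p = 0.124 with an estimated correlation). Thbs2, thrombospondin 2, was 9.70-fold and Lox, the collagen cross-linking lysyl oxidase, 7.26-fold higher. All 13 endothelial genes were higher, also when adjusted over the list alone, with a mean of 1.31 and with Cdh5, VE-cadherin (4.27-fold), and Emcn, endomucin (4.09-fold), in front (camera adjusted p = 9.26e-12, and adjusted p = 0.124 with an estimated correlation). Of 24 genes of the TGF-beta pathway and its targets 11 were higher and none lower, 16 higher when adjusted over the list alone, with a mean of 0.91 (camera adjusted p = 6.42e-09, and adjusted p = 0.124 with an estimated correlation). Tgfbr2, itself inactivated in the epithelium of these mice, is among the 11. Ltbp2, a latent TGF-beta binding protein family gene, was 5.65-fold and Ccn2, a connective tissue growth factor gene, 4.07-fold higher. Ltbp2 was at 8.02 in cancer 3 and between 9.60 and 10.60 in the other cancers. Several of these genes are made by more than 1 cell type, and the lists share 13 of their 544 genes.

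**Figure D3:**
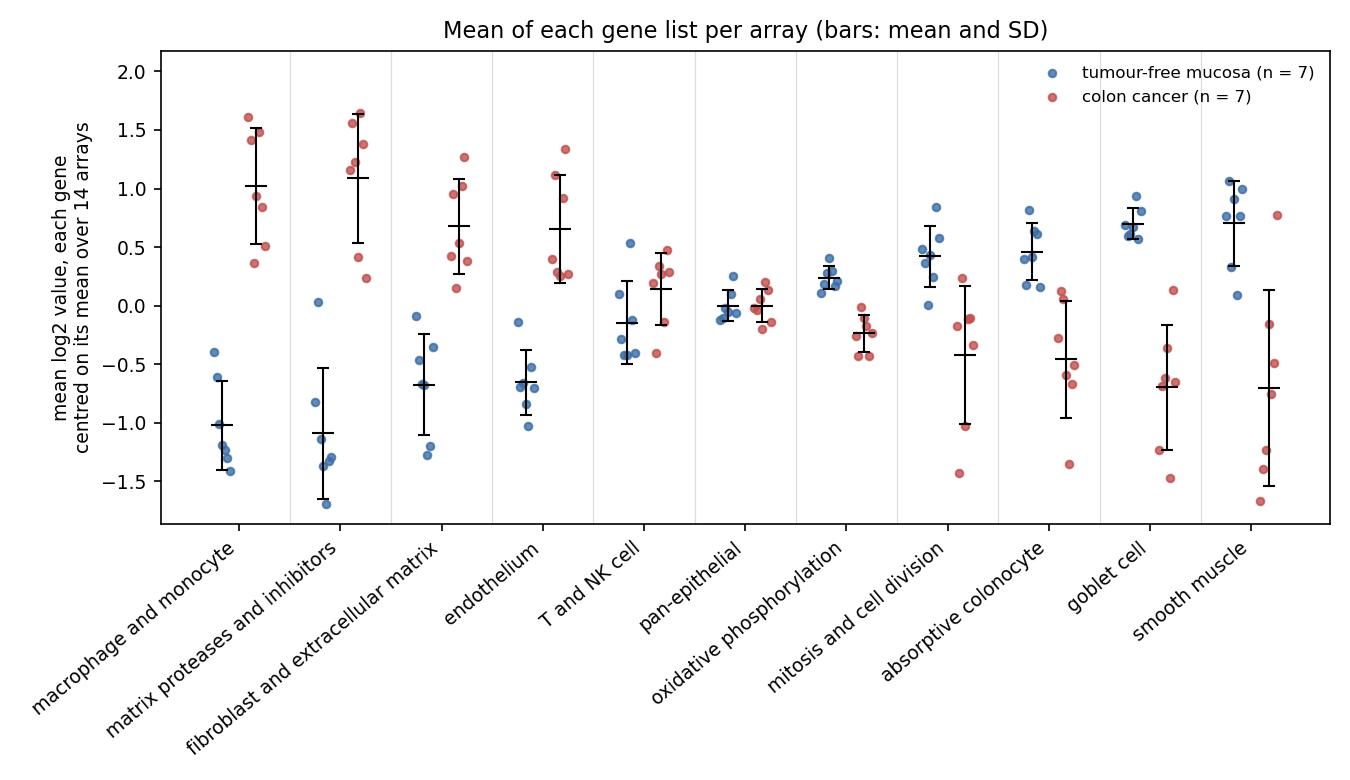
Mean of 11 gene lists in each array, with every gene centred on its mean over the 14 arrays, in log2 units, mucosa in blue, cancers in red, and bars for the mean and SD of 7 arrays. The macrophage list averaged 1.02 ± 0.49 in the cancers and -1.02 ± 0.38 in the mucosa, and the pan-epithelial list 0.00015 ± 0.14 and -0.00015 ± 0.13.

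Smooth muscle genes were lower in the cancers on average, but not in cancer 7. On the centred smooth muscle mean cancer 7, at 0.77, lay within the mucosa range of 0.09 to 1.07. The other cancers, at -1.67 to -0.15, lay below that range. Of 14 measured members 10 were lower and none higher, 13 lower when adjusted over the list alone, and the mean log2 difference was -1.41 (camera adjusted p = 1.51e-06, and adjusted p = 0.302 with an estimated correlation). Cnn1, calponin of smooth muscle, was 5.81-fold and Actg2, enteric smooth muscle actin, 4.87-fold lower, with 6 of 7 cancers below all mucosa arrays for both. Of 13 enteric neuron and glia genes 3 were lower, 4 when adjusted over the list alone, and none was higher, with a mean of -0.35 that was not past its test (camera adjusted p = 0.0737, and adjusted p = 0.621 with an estimated correlation). Among the 3 were Snap25, a synaptic protein gene (7.17 ± 0.51 in the cancers and 8.17 ± 0.45 in the mucosa), and Vip, the gene of vasoactive intestinal peptide (log2 difference -1.69). Without cancer 6, cancer 7 or mucosa 3 the list passed (camera adjusted p = 0.0493, 0.0300 and 0.00912). It also passed after cyclic loess scaling (0.0476), with the replicate number as a block (0.0451) and in the exact permutation of its mean (adjusted p = 0.0448). The count of lower neuron and glia genes was 1 without cancer 1, cancer 2, cancer 6 or mucosa 7, and 6 without mucosa 3. Of 9 adipocyte genes 1 was higher and 1 lower, also when adjusted over the list alone, with a mean of 0.20 that turned to -0.28 without cancer 2 (camera adjusted p = 0.482, and adjusted p = 0.847 with an estimated correlation). These were Lpl, lipoprotein lipase (1.44), and Pck1, which is also made by the colonic epithelium (-1.54, and -2.13 without cancers 2 and 4). Leaving out cancer 2 and both arrays numbered 5, which stood apart in other genes, gave 6 smooth muscle genes lower and no neuron or glia gene (Snap25, limma adjusted p = 0.0741). Vip, Pck1 and Lpl missed the threshold in 10, 9 and 4 of the 14 fits that each left out 1 array.

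Goblet cell genes were lower in the cancers, and of the absorptive colonocyte, enteroendocrine and pan-epithelial lists fewer members were past the threshold. Of 16 goblet cell genes 13 were lower and none higher, also when adjusted over the list alone, with a mean log2 difference of -1.39 (camera adjusted p = 2.80e-10, and adjusted p = 0.124 with an estimated correlation). Spdef, a transcription factor of goblet cell maturation, was 5.22-fold lower, with each cancer below all mucosa arrays. Of 24 absorptive colonocyte genes 8 were lower and none higher, 8 lower and 1 higher when adjusted over the list alone, with a mean of -0.92 (camera adjusted p = 0.000502, and adjusted p = 0.292 with an estimated correlation). Fabp2 and Cyp2c55 led this list. Of 15 enteroendocrine genes 5 were lower, also when adjusted over the list alone, with a mean of -0.58, among them Pcsk1, a prohormone convertase gene (5.11-fold lower), and Sst, somatostatin (2.37-fold lower) (camera adjusted p = 0.00804, and adjusted p = 0.302 with an estimated correlation). The 14 pan-epithelial genes had a mean of 0.00029 and a median of -0.04, with 2 higher and 3 lower, or 4 lower when adjusted over the list alone (camera adjusted p = 0.863 on the lower side, and adjusted p = 0.942 with an estimated correlation). The sign of that mean changed in 8 of the 14 fits that each left out 1 array. Cldn4, a tight junction claudin gene, rose by 2.49, whereas Cdx2, an intestinal transcription factor gene, fell by 1.74 and Tspan8 fell by 0.48. Epcam (log2 difference -0.03), Krt8 (-0.05) and Cdh1 (0.29) were not past the threshold. Of the 17 antimicrobial and mucosal defence genes 1 was higher, Slpi, a secreted protease inhibitor gene (2.25-fold), and 3 lower, also when adjusted over the list alone, with a mean of -0.11 (camera adjusted p = 0.929, and adjusted p = 0.962 with an estimated correlation). Slpi missed the threshold in the exact rank test (adjusted p = 0.107) and without cancers 2 and 4 (limma adjusted p = 0.0861), and 2 of 7 cancers lay above all mucosa arrays. Without mucosa 2 the defence list had 4 genes higher and 3 lower with a mean of -0.01. The mean was -0.25 without cancer 3 or after centring on the median, -0.04 without cancer 1 and -0.0009 without cancer 5. The enteroendocrine count was 2 or 3 in 12 of the 14 fits that each left out 1 array, 2 without cancer 2 and both arrays numbered 5, and after centring on the median the list was not past its test (camera adjusted p = 0.0906). Sst and Tspan8 missed the threshold in 6 and 2 of those fits, Sst also without cancer 2 and both arrays numbered 5 (limma adjusted p = 0.117) and Tspan8 after quantile (0.0671) or cyclic loess scaling (0.0910).

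Markers of other epithelia were mostly not past the tests. The 6 Paneth cell genes held 1 increase, Lyz1, a lysozyme gene (2.79), and 1 decrease, Pla2g2a, a secreted phospholipase gene (-2.79), with 3 higher and 1 lower when adjusted over the list alone and a mean of 0.51 (camera adjusted p = 0.374, and adjusted p = 0.734 with an estimated correlation). Lyz2, also a lysozyme gene, is on the macrophage list, which was higher, and which cells gave the Lyz1 signal was not tested. Cancer 3 was at 2.28 on the centred Paneth mean against -0.87 to 0.29 in the other cancers. Without it the mean was 0.17. Without cancer 1, 3 Paneth cell genes were higher. Of 11 tuft cell genes Fyb (1.72) and Lrmp (1.03), which leukocytes also express, were higher and 2 were lower, including Rgs13 (at least 2.81-fold, 3 of 7 cancers being at the level of absent transcripts), also when adjusted over the list alone, with a mean of -0.08 that turned to 0.0020 without mucosa 6 (camera adjusted p = 0.478, and adjusted p = 0.807 with an estimated correlation). Of 14 small intestinal enterocyte genes Anpep, an aminopeptidase gene, was higher (2.68) and Alpi (-2.12) and Mep1a (-1.21) were lower, also when adjusted over the list alone (camera adjusted p = 0.478, and adjusted p = 0.837 with an estimated correlation). The mean of that list, 0.14, turned to -0.0020 after centring on the median and to -0.0606 without cancer 5. Of 13 gastric mucosa genes Vsig1 (1.45) was higher and Muc6 (-0.71) lower, with 1 and 2 when adjusted over the list alone, and the mean of 0.01, the median of -0.05 and the test, on the lower side, differed in sign, the mean being negative without cancer 3, mucosa 2 or mucosa 5 (camera adjusted p = 0.563, and adjusted p = 0.761 with an estimated correlation). Of 15 squamous epithelium genes Lor (at least 1.96-fold) and Krt4 (at least 1.74-fold), with 1 and 2 mucosa arrays at the level of absent transcripts, were higher, also when adjusted over the list alone, and the mean of 0.22 and the test lay on the higher side and the median, -0.0047, did not (camera adjusted p = 0.374, and adjusted p = 0.658 with an estimated correlation). Without cancer 2 and both arrays numbered 5, Alpi differed by -2.79, Mep1a (limma adjusted p = 0.0996) and Rgs13 (0.0543) missed the threshold and no tuft cell gene was lower. Without cancers 2 and 4 no small intestinal gene was lower. Alpi, Lrmp and Vsig1 missed the threshold in 10, 9 and 9 of the 14 fits that each left out 1 array.

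A list of fetal-like and regenerative epithelial genes, among them Clu and Msln, was higher in the cancers. Of its 12 measured members 6 were higher and none lower, 9 higher when adjusted over the list alone, with a mean log2 difference of 1.37 (camera adjusted p = 3.84e-06, and adjusted p = 0.138 with an estimated correlation). Its members Ccn2 and Plaur are also on the TGF-beta and matrix protease lists, which were higher too. The values are from bulk tissue, so whether epithelial cells gave the rise was not tested. Msln was at 9.05 in mucosa 1 and between 6.45 and 7.04 in the other mucosa arrays. Of 21 Wnt/beta-catenin target genes 6 were higher and none lower, also when adjusted over the list alone, with a mean of 0.36 (camera adjusted p = 0.00416, and adjusted p = 0.302 with an estimated correlation). The largest increases were in Wif1 (2.53-fold) and Dkk2 (1.98-fold), both secreted proteins that act on Wnt signalling. Of 13 intestinal stem cell genes Rnf43 (0.90) and Cdk6 (0.82) were higher and Rgmb (-0.71) lower, with 2 on each side when adjusted over the list alone (camera adjusted p = 0.622, and adjusted p = 0.860 with an estimated correlation). Of these 13 stem cell genes 7, Rnf43 among them, are also on the Wnt target list, so the 2 lists are not independent. The mean of the stem cell list was 0.11 and turned to -0.03 after centring on the median. It was 0.03 without mucosa 2 and 0.20 without mucosa 1. No stem cell gene was higher without cancer 1, 6 or 7 or mucosa 2, 4 or 7. Of 13 p53 target genes 5 were higher and none lower, also when adjusted over the list alone, with a mean of 0.44 (camera adjusted p = 0.00476, and adjusted p = 0.243 with an estimated correlation). Phlda3 was 3.14-fold and Trp53inp1 2.12-fold higher, and 3 members were higher without cancer 2 and both arrays numbered 5. The Wnt mean was 0.22 after centring on the median. With genes of below-median mean intensity left out, the Wnt and p53 lists were not past their tests (camera adjusted p = 0.0774 and 0.0560). Trp53inp1, Cdk6 and Rnf43 missed the threshold in 9, 8 and 6 of the 14 fits that each left out 1 array.

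Genes of mitosis were lower in the cancers. Of 25 measured mitosis and cell division genes 18 were lower and none higher, 24 lower when adjusted over the list alone, with a mean log2 difference of -0.84 (camera adjusted p = 1.31e-09, and adjusted p = 0.302 with an estimated correlation). Kif11, a spindle motor gene, was 2.20-fold lower with each cancer below all mucosa arrays, Top2a, a topoisomerase gene, was 2.16-fold lower, and Mki67, which encodes the Ki-67 proliferation marker, 1.99-fold lower. The 7 cancers ranged from -1.43 in cancer 2 and -1.03 in cancer 4 to 0.23 in cancer 3 on the centred list mean, and the mucosa from 0.01 to 0.84. A less intense row for Top2a gave a difference of -0.20, and with the rows averaged Top2a was not past the threshold (limma adjusted p = 0.0520). Of 25 DNA replication genes 6 were lower and none higher, 7 lower when adjusted over the list alone, with a mean of -0.41 (camera adjusted p = 0.000135, and adjusted p = 0.477 with an estimated correlation). They included Tyms, thymidylate synthase (1.67-fold lower), and Prim1, a primase gene (1.59-fold lower). Of 16 DNA mismatch repair genes 4 were lower and none higher, 7 lower when adjusted over the list alone, with a mean of -0.23 (camera adjusted p = 0.0496, and adjusted p = 0.621 with an estimated correlation). Exo1, an exonuclease gene (1.58-fold), and Pold2, a DNA polymerase subunit gene (1.47-fold), fell most among them, and Exo1 missed the threshold without cancers 2 and 4 (limma adjusted p = 0.0603), as did Tyms (0.0617). Single arrays moved these counts: 10 or 11 mitosis genes were lower without mucosa 6 or 7, DNA replication genes ranged from 2 without cancer 2 or mucosa 6 to 10 without cancer 3, and mismatch repair genes from 1 without mucosa 4 to 6 without cancer 3. Without cancers 2 and 4 together 9 mitosis genes, no DNA replication gene and no mismatch repair gene were lower. The mismatch repair list shares Pcna and Rfc3 with the DNA replication list and holds further genes of DNA synthesis, such as Pold2, while Msh2 was not analysed. Its fall was thus not separated from that of the replication genes. The mismatch repair list was not past its test in 6 of the 14 fits that each left out 1 array (camera adjusted p up to 0.121). Nor was it past the test after centring on the median (0.107) or with the replicate number as a block (0.0703). Pold2 and Prim1 missed the threshold in 8 and 5 of those 14 fits, and Prim1 also with the block (limma adjusted p = 0.0838). The list means were -0.52 for mitosis, -0.21 for DNA replication and -0.12 for mismatch repair without cancers 2 and 4. Mismatch repair was not past its test there (camera adjusted p = 0.307), nor without cancer 2 and both arrays numbered 5 (0.0964).

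Oxidative phosphorylation genes were lower. Of 25 oxidative phosphorylation genes 18 were lower and none higher, 22 lower when adjusted over the list alone, with a mean log2 difference of -0.47 (camera adjusted p = 1.77e-11, and adjusted p = 0.124 with an estimated correlation). Uqcrfs1, the Rieske protein gene of complex III, was 1.62-fold and Atp5o, an ATP synthase subunit gene, 1.61-fold lower. Of 14 fatty acid oxidation and ketogenesis genes 7 were lower and none higher, also when adjusted over the list alone, with a mean of -0.35 (camera adjusted p = 0.000806, and adjusted p = 0.302 with an estimated correlation). Acads, short-chain acyl-CoA dehydrogenase, fell by 1.12 (SE 0.13) with each cancer below all mucosa arrays, and Ppara, a nuclear receptor gene of fatty acid catabolism, fell by 0.63. None of the 14 glycolysis genes was past the threshold, over all genes or adjusted over the list alone, and their mean of 0.11 turned to -0.03 after centring on the median (camera adjusted p = 0.478, and adjusted p = 0.845 with an estimated correlation). Slc16a3, a lactate transporter gene, had the smallest adjusted p of them in limma (log2 difference 0.76, adjusted p = 0.199). The glycolysis mean was 0.20 without cancer 4, where 1 gene was higher, and 0.06 without mucosa 5. The fatty acid count was 2 without cancer 6, 3 without mucosa 5 or 6, 4 without cancer 4 or mucosa 3, 3 without cancer 2 and both arrays numbered 5, and Ppara and Uqcrfs1 missed the threshold in 10 and 8 of the 14 fits that each left out 1 array. Uqcrfs1 also missed it after quantile (limma adjusted p = 0.0619) or cyclic loess scaling (0.0727).

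Among immune genes other than those of macrophages, fewer members passed. Of 12 neutrophil genes 4 were higher and none lower, 5 higher when adjusted over the list alone, with a mean log2 difference of 1.21 (camera adjusted p = 8.80e-05, and adjusted p = 0.302 with an estimated correlation). Mmp9, a gelatinase gene that macrophages also express, was 6.20-fold and Clec4d, a myeloid lectin gene, at least 5.37-fold higher, with 3 of 7 mucosa arrays at the level of absent transcripts. Without cancer 2 and both arrays numbered 5 Mmp9 was 3.77-fold higher. Of 19 inflammatory cytokine and chemokine genes 5 were higher and none lower, also when adjusted over the list alone, with a mean of 0.67 (camera adjusted p = 0.00520, and adjusted p = 0.463 with an estimated correlation). Il1a was at least 5.04-fold higher, with 6 of 7 mucosa arrays at the level of absent transcripts, and Ccl3 was 5.83-fold higher. In mucosa 2 they were at 8.53 and 9.90, against 4.61 to 5.05 and 5.51 to 7.05 in the other mucosa arrays. Both missed the threshold in the exact rank test (adjusted p = 0.0623 and 0.107). Without mucosa 2 the counts were 9 neutrophil genes and 8 cytokine and chemokine genes. Of 14 immune checkpoint and regulatory T cell genes 4 were higher and none lower, 5 higher and 1 lower when adjusted over the list alone, with a mean of 0.43 (camera adjusted p = 0.00106, and adjusted p = 0.302 with an estimated correlation). Havcr2, which encodes TIM-3 and is also made by myeloid cells, was 2.92-fold and Il2ra, the CD25 gene, 2.31-fold higher. Of 15 T and NK cell genes 1 was higher, Cd3g (2.32-fold), and of 13 B and plasma cell genes 1, Cd22 (2.15-fold), in both cases also when adjusted over the list alone. Cd3g missed the threshold in the exact rank test (adjusted p = 0.0835). The means were 0.29 for T and NK cells (camera adjusted p = 0.0484, and adjusted p = 0.621 with an estimated correlation) and 0.38 for B and plasma cells (camera adjusted p = 0.0318, and adjusted p = 0.621 with an estimated correlation). Without cancer 2 and both arrays numbered 5, 7 checkpoint, 5 T and NK cell and 2 B and plasma cell genes were higher, with means of 0.57 for T and NK cells and 0.70 for B and plasma cells. Without cancer 7 the B and plasma cell mean was 0.19, and after centring on the median the means were 0.15 and 0.24. The T and NK cell list was not past its test in 9 of the 14 fits that each left out 1 array (camera adjusted p up to 0.109) nor after quantile (0.0542) or cyclic loess scaling (0.0610), and the B and plasma cell list in 4, namely without cancer 4 (0.0920), cancer 7 (0.238), mucosa 2 (0.0570) or mucosa 6 (0.0509). With genes of below-median mean intensity left out, the cytokine, checkpoint and B and plasma cell lists were not past their tests (camera adjusted p = 0.126, 0.595 and 0.595). Of 19 interferon response genes Psmb8 (-0.68) and Psmb9 (-0.80), subunits of the immunoproteasome, were lower and none was higher, also when adjusted over the list alone, with a mean of -0.15 that turned to 0.0268 without mucosa 5 (camera adjusted p = 0.258, and adjusted p = 0.788 with an estimated correlation). None of the 6 MHC class II genes was past the threshold, over all genes or adjusted over the list alone, and their mean of -0.07 turned to 0.14 without cancer 2 and was also positive without mucosa 6 (camera adjusted p = 0.945, and adjusted p = 0.976 with an estimated correlation). H2-Eb1 differed by 0.26 (limma adjusted p = 0.580). Of 10 mast cell genes Cma1, a chymase gene, was higher (5.60 against 5.17 in the mucosa, where it was at the level of absent transcripts, so at least 1.14-fold) and Kit, which interstitial cells of the muscle layer also express, was lower (-1.35), with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.374, and adjusted p = 0.734 with an estimated correlation). The mast cell mean of 0.07 turned to -0.07 after centring on the median and was also negative without cancer 5 or cancer 6, and Cma1 missed the threshold after that centring (limma adjusted p = 0.109) and in 11 of the 14 fits that each left out 1 array.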

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

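The tests of a lower epithelial share, of single cancers and of less muscle layer were chosen only after the results were seen. So were those of RNA from a female animal and of a wrong label. Those of scaling and of other splits were chosen before. The test of an extra X chromosome was set before its result, but for a pattern in cancer 2 that was itself found in these data. For 90 named genes and 36 lists in each tissue, an array was singled out where its gap to the nearest array took up an unusually large part of the range of its 7 arrays. This held in 32 of 252 groups, or 12.7%, where chance gives about 5% for independent normal values, and mucosa 1 and mucosa 2 held 8 each. Named genes and lists overlap and vary together, so the 32 are not separate outliers, and the excess over 5% was not tested. List values below are means of log2 values with each gene centred over the 14 arrays.

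In mucosa 1, Khdc1a was at 8.89 (others 4.25 to 6.00), Msln at 9.05 (6.45 to 7.04), Slpi at 9.13 (6.96 to 7.81), C1qc at 9.39 (8.10 to 8.58) and Havcr2 at 6.78 (5.83 to 6.22), all above the other mucosa arrays. Fabp2 at 10.73 (12.02 to 12.83) and Col10a1 at 6.22 (6.76 to 7.12) lay below them, and the B and plasma cell list at 0.43 (-0.43 to -0.19) above. The genes Khdc1a, Msln, C1qc, Havcr2, Slpi and Fabp2 thus lay on the side of the cancers in this array, and Col10a1 on the other side. In mucosa 2, Il1a was at 8.53 (4.61 to 5.05), Ccl3 at 9.90 (5.51 to 7.05) and Clec4d at 7.61 (5.09 to 5.59), with the neutrophil list at 1.59 (-1.12 to -0.75) and the cytokine and chemokine list at 1.01 (-0.73 to -0.31). The same array was lowest for H2-Eb1 at 10.55 (11.66 to 12.48), Kit at 8.29 (9.55 to 10.42) and the MHC class II list at -1.22 (-0.08 to 0.60). In mucosa 3, Serpinb11 was at 4.37 (4.00 to 4.14) and the enteric neuron and glia list at -0.38 (0.15 to 0.46). In mucosa 5, the small intestinal enterocyte list was at 1.25 (-0.48 to 0.01), and Vsig1 at 5.44 (7.85 to 9.21), Pla2g2a at 7.72 (9.79 to 11.19) and Cnn1 at 11.07 (12.20 to 12.96) were low.

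Among the cancers, cancer 2 had the adipocyte list at 2.93 (others -0.67 to 0.08), the MHC class II list at -1.26 (-0.11 to 0.50), H2-Eb1 at 10.90 (12.16 to 12.57) and Psmb8 at 9.23 (9.87 to 10.27). Cancer 3 had Col10a1 at 7.43 (10.52 to 12.23), Ltbp2 at 8.02 (9.60 to 10.60) and the Paneth cell list at 2.28 (-0.87 to 0.29). Sst was at 9.06 in cancer 4 (7.24 to 7.88), and cancer 5 had Abca12 at 7.74 (5.29 to 6.01) and Trp53inp1 at 9.39 (10.99 to 11.42).

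The lower level of mitosis genes in cancers than in mucosa was weighed against 3 technical explanations. A lower epithelial share in the cancers would pull down all pan-epithelial markers alike. The mitosis list fell further than the pan-epithelial list by a log2 difference of -0.84 (SE 0.22, exact permutation p = 0.00175). As the pan-epithelial mean was 0.00029, this nearly restates the fall of the mitosis list, and both means had been seen. For 12 of the 14 markers the 95% interval lay above the mean fall of the mitosis list. The markers moved both ways (SD over markers 0.88, Cldn4 2.49 and Cdx2 -1.74), so they gauge the epithelial share only roughly. Cancers 2 and 4 were the lowest, and without them the mean was still -0.52 (exact permutation p = 0.00631), although 9 rather than 18 members were then past the threshold. Under median centring, quantile and cyclic loess scaling the mean nearest to 0 was -0.88 with a camera adjusted p of at most 2.41e-06, against a range up to 0.302 over all alternatives. A lower share of dividing cells in the cancers is a hypothesis that these bulk values do not test, and a lower share of dividing crypt cells among the epithelial cells would give the same values.

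Macrophage, fibroblast and endothelial lists were higher in the cancers and the smooth muscle list lower. A lower epithelial share on its own would raise all of them alike. The macrophage and smooth muscle lists moved apart by a log2 difference of 3.45 (SE 0.48, exact permutation p = 0.000583). That p is the smallest that 3432 splits can give. These lists were set against each other after they were seen to move in opposite directions, so the p nearly restates that choice. A lower epithelial share together with less muscle layer would give the same pattern. The test therefore cannot exclude a lower share, which stays open. The lowest mean of the 3 raised lists under the other scalings was 1.17, with camera adjusted p of at most 1.10e-10 against a range up to 0.124 over all alternatives, so scaling was not the whole of it. Less muscle layer in the cancer pieces may account for the smooth muscle genes and stays open. The cells of the neuron and glia list lie only in part in and between the muscle layers, so the list follows these layers only roughly. It shifted by -0.35 with a camera adjusted p of 0.0737 (0.00912 to 0.621 over the alternatives). The list was past the test after cyclic loess scaling (0.0476), with the replicate number as a block (0.0451) and by exact permutation (adjusted p = 0.0448). More macrophages and matrix-producing cells in the cancers, as against more RNA of these genes per cell, was not tested.

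Cancer 2 held Xist, the RNA of the inactive X chromosome, at 9.76 together with Y-linked Eif2s3y at 8.73, Uty at 8.53 and Kdm5d at 7.85, whereas each of the other 13 arrays held Xist or Y-linked RNA but not both. A swap or wrong label would bring 1 of the 2 signals, but both lay at least 2.44 log2 units above the arrays that lacked them. RNA of a female animal mixed in is a candidate explanation that stays open: the Y-linked genes lay -0.47 from the mean of the other Y-positive cancers and 2 of the 3 below all of these, where the Xist level, with a share of 38.7%, would give -0.71. An extra X chromosome in the animal or in a tumour clone may also account for it, and X-linked genes that escape inactivation differed by -0.0047 from the other Y-positive cancers. They were set to exclude it at or below 0, but this bound was wrong, because the Xist-positive cancers differed from the Y-positive ones by only 0.06 (SD over 5 genes 0.18), so the test cannot separate the cases. It was also to be excluded by Y-linked genes below all the other Y-positive cancers, which their mean met (-0.47, the lowest of these being at -0.03) but only 2 of the 3 genes did, so it stays open.

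Of 100 splits of the 14 arrays into 7 and 7, only the real 1 gave as many called genes, 3548 against 2671 for the highest other. Only the real 1 gave as many genes changed at least 2-fold, 1078 against 791. Chance is thus unlikely for both counts, at 1 of 100, the smallest share that these splits can give. The highest other split differed from the real one by exchanging cancer 3 and mucosa 1. For the gene lists 6 of 100 splits gave as many lists past the camera test, 22 in the real split and 26 in the highest other, with a median of 14 over the other 99, so chance cannot be excluded for the number of lists. The mean of each list was also tested by exact permutation with Benjamini-Hochberg adjustment over the lists, which gave 12 lists higher and 10 lower, with squamous epithelium (adjusted p = 0.0126) and neuron and glia (0.0448) gained and T and NK cells (0.204) and B and plasma cells (0.316) lost. The adjusted p was 0.00210, the smallest found, for the macrophage, matrix protease, fibroblast, endothelial, TGF-beta, fetal-like, p53, goblet, colonocyte and oxidative phosphorylation lists, 0.00381 for mitosis and 0.00968 for smooth muscle.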

How the results depend on the processing

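The fits without cancer 2 and both arrays numbered 5, without cancers 2 and 4, and the permutation of list means were chosen only after the results were seen. Under the alternatives 60 of 88 called named genes kept their call in every setting run and 0 changed sign, and leaving out single arrays gave 1638 to 2241 genes higher, 1110 to 1669 lower, 727 to 885 and 258 to 329 at least 2-fold, 11 to 13 lists higher and 8 to 10 lower. Centring on the median gave 5475 genes lower and 440 at least 2-fold lower, and array weights 2576 lower. The filter on genes above the median mean gave 1336 higher, 971 lower and 6 lists higher, with fewer genes tested, and also ended the calls of the enteroendocrine (camera adjusted p = 0.0657) and mismatch repair lists (0.0503). Fry, directional, ended those of T and NK, B and plasma, cytokine and mismatch repair genes (adjusted p = 0.0884 to 0.259). A threshold of 0.01 gave 1230 and 615, and limma's treat against 1.5-fold 387 and 98, both stricter by construction. Camera with an estimated correlation gave 0 lists higher and 0 lower, against 22 with the preset one. The estimated correlations of these lists were 0.120 to 0.799, and that test also uses fewer degrees of freedom, so which of these changed the result was not tested. List means that changed sign were, after median centring, intestinal stem cell -0.0334, small intestinal -0.0020, gastric -0.13, pan-epithelial -0.14, mast cell -0.0702 and glycolysis -0.0349, and after quantile scaling gastric -0.0056. Without cancer 2 and both arrays numbered 5 they were tuft 0.0250, gastric -0.0047, pan-epithelial -0.0176, adipocyte -0.17, MHC class II 0.23 and glycolysis -0.0307, and without cancers 2 and 4 adipocyte -0.34 and MHC class II 0.12. Leaving out single arrays moved the mean of adipocyte genes from -0.28 to 0.33, MHC class II from -0.27 to 0.14, gastric from -0.0275 to 0.0362, pan-epithelial from -0.0338 to 0.0430, small intestinal from -0.0606 to 0.36, mast cell from -0.0204 to 0.14, interferon from -0.24 to 0.0268 and tuft from -0.13 to 0.0020. None of these lists was past its test, and the cause was not tested.

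Arrays with the same replicate number deviated together with r above 0.1 in 5 of 7 pairs (mean 0.23, against -0.04 for other numbers), and 6 of 14 arrays correlated best with their own number. Xist and Y-linked signals pointed the same way in the cancer and mucosa of each number, except that cancer 2 held both, a hint from the data and not from the design. With the replicate number as a block 2356 genes were higher and 1717 lower, 813 and 288 by at least 2-fold, and 3260 of the 3548 calls were shared. The block gave 13 lists higher and 9 lower, with mismatch repair no longer past its test (camera adjusted p = 0.0703) and neuron and glia past it (0.0451), and ended the calls of Prim1 (limma adjusted p = 0.0838), Ppara (0.0804), Pck1 (0.0600) and Cdk6 (0.0522). The exact rank test ended 18 named-gene calls, with adjusted p from 0.0623 to 0.168. Fits without the 3 arrays shared 2340 of 2515 calls with those reported, and fits without cancers 2 and 4 shared 2689 of 2918. The leading count of members moved by over 1.5 times without some array in 21 lists, of which 18 had a count of 5 or fewer. Signal over background limits weak genes, and no detection call was at hand to mark them.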

Other observations

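The lists in this part and their tests were chosen only after the results were seen. Enzymes of mucin O-glycosylation, which include A4gnt and B3gnt6, moved both ways: of 24 measured genes 12 were lower, 2 higher and 10 not past the threshold, 15 and 3 when adjusted over the list alone, with a mean log2 difference of -0.80 (camera adjusted p = 3.44e-06, Benjamini-Hochberg over 5 lists, and adjusted p = 0.0436 with an estimated correlation). Of 25 genes of steroid and xenobiotic metabolism, which include Cyp2c55, Cyp2c65 and Akr1c21, 15 were lower and 2 higher, also when adjusted over the list alone, with a mean of -1.30 (camera adjusted p = 3.05e-06, and adjusted p = 0.0495 with an estimated correlation). Of 19 genes of osteoclasts and of the lysosomes of macrophages, which include Atp6v0d2, Gpnmb and Ctsk, 13 were higher and none lower, 14 when adjusted over the list alone, with a median of 1.22 (camera adjusted p = 3.39e-11, and adjusted p = 0.0436 with an estimated correlation). These 3 lists hold genes already seen to differ in these samples, so their tests are not independent evidence. Of 14 cytosolic ribosome genes none was past the threshold, with a mean of 0.02 (camera adjusted p = 0.439, and adjusted p = 0.743 with an estimated correlation).

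Genes that mark the position along the gut differed between single arrays, and Hoxb13 and Hoxd13 in part also between the tissues. Position was not a term in the fit, so for genes that vary along the gut it was not separated from tissue. Of 15 posterior HOX genes 2 were higher and 1 lower, also when adjusted over the list alone, with a mean of 0.45 (camera adjusted p = 0.134, and adjusted p = 0.143 with an estimated correlation). Hoxd13 was at 10.53, 10.28 and 11.24 in cancers 1, 4 and 7, and between 5.75 and 6.90 in the other 11 arrays. Hoxb13 was at 5.54 in cancer 5 and at 9.87 or above in the other cancers, and it was at 10.69 in mucosa 1 and between 6.21 and 9.03 in the other mucosa arrays. Sis, sucrase-isomaltase of the small intestine, was at 10.10 in cancer 5 and 8.67 in mucosa 5, and at 5.21 or below elsewhere. Fabp6, the ileal bile acid binding protein gene, was at 12.22 in mucosa 5 and at 6.18 or below in every other array, cancer 5 included. Slc10a2, the ileal bile acid transporter gene, was at 10.83 in cancer 5 and 10.45 in mucosa 5 but also at 9.77, 9.49 and 8.82 in cancers 1, 2 and 3 and at 9.56 in mucosa 3. In cancer 2 the adipocyte genes Adipoq and Plin1 were at 11.04 and 9.67, above 7.73 and 7.30, their highest values in the other arrays, and Pnliprp1, a pancreatic lipase-related gene, was at 11.01, against 8.63 in cancer 3 and 6.00 or below elsewhere. All of these genes were chosen after their values were seen.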
